A study of Mus musculus with 60 samples.

How the data were processed

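Hepatic transcripts were measured on nylon macroarrays, membranes on which cDNA fragments of chosen genes are spotted and hybridized with radioactively labelled cDNA. Per the labels, liver RNA came from 60 male mice on the C57BL/6J background, 10 in each of 6 groups, with 1 mouse per array, so the replicates were separate animals. Wild-type and PPARα-null mice received corn oil alone or di-(2-ethylhexyl)-phthalate (DEHP), a plasticizer, at 20 or 200 mg/kg per day by gavage for 21 days. Wild-type mice were 21 weeks old and null mice 23 to 25 weeks old at sampling per the labels, so genotype and age cannot be told apart. Per the labels' protocols, RNA was extracted with TRIzol from a liver piece of about 100 mg, and 5 µg of total RNA with 13 yeast spike-in mRNAs was reverse-transcribed with 33P-labelled nucleotide.

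Each deposited array table held 1 signal column, a spot intensity on a linear scale that per the file headers still included the background. Of the 768 spots on an array, 451 held only solvent (DMSO), 295 held mouse cDNA and 22 held yeast cDNA. The imaging software is not given in the sources used here. A value table of the whole series held the authors' processed log2 values for 265 mouse spots, and 30 mouse spots were not in it. Set against the array tables, each deposited log2 value equalled the log2 intensity minus the mean log2 intensity of 21 yeast spots of the same array, without background subtraction. This match left a largest residual of 0.006 on the log2 scale for 263 entries. The remaining 2 entries were exchanged between the spots at positions 9L and 13H, so the identity of those spots is disputed and they are named here by position and kept out of the gene lists. The column medians of the value table lay between -5.23 and -4.12.

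Background was corrected with the nec function of limma, which fits a normal-exponential model with the DMSO spots as negative controls, with an offset of 50. Signals were put on the log2 scale and quantile-normalized over the 295 mouse spots of the 60 arrays, and yeast and DMSO spots were then left out. Quantile normalization sets the values of the brightest spots by their rank, so exchanges of rank among the few brightest spots, such as Apoe, Fabp1, Mup2, Cyp2c29 and, in null mice, Apoa4, appear as steps. A probe was tested where its uncorrected intensity exceeded the DMSO mean plus 2 SD on at least 5 of the 10 arrays of at least 1 group, which left 147 probes with 146 distinct symbols. "Above background" refers to this limit throughout. Where every array of a group lay below it, the fold is given only as "at least N-fold", computed against the higher of the probe's own signal and the lowest signal above background on each array, and no fold is given where that ratio was under 1. An interaction with such a group in it is a difference of fitted signals and measures no fold. Where only 1 or 2 arrays of a group lay above background, a fold rests on signal near background on that side and its size depends on the background correction.

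A linear model with 6 group means was fitted to all 60 arrays with lmFit and eBayes of limma (prior 6.58 degrees of freedom, 60.6 in total). Comparisons were each dose against vehicle within a genotype, null against wild type under vehicle, both genotype-by-dose interactions and 200 against 20 mg/kg within a genotype. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05, and every adjusted p without another name comes from this fit. Folds are given with 95% intervals and log2 changes with the standard error (SE). The number of arrays limits the precision of every value.

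Lists of genes were fixed before the data were examined, as were the tests, the naming rule and the first set of alternatives. The 14 lists covered microsomal and peroxisomal fatty acid oxidation, mitochondrial fatty acid oxidation and ketogenesis, fatty acid uptake, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, bile acid synthesis and transport, drug metabolism of the type controlled by the receptors CAR and PXR, the AhR and oxidative stress response, glucose metabolism, nuclear receptors, lipoproteins and lipases, inflammation, cell cycle and stress, and reference transcripts. Markers of other cell types were fixed as well. The 12 lists with at least 3 tested probes were tested with fry of limma, adjusted over lists within a comparison. This test asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. The counts "adjusted over the list alone" use only the probes of that list. Named genes were the 12 largest increases and 12 largest decreases past the threshold in a comparison (6 and 6 for interactions and dose contrasts), Ppara in every group, Cyp4a14, Cyp4a10, Cyp2b10, Cyp3a11 and Fasn in every comparison, and up to 4 members of each list with the lowest p. Some genes that the rule names are not reported here, although they count in the totals and lists. A gene with several probes was named by its brightest probe.

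Spot names were updated through gene identifiers or accessions with a table of mouse genes of assembly GRCm38.p6, used for names only. This named 285 mouse spots, changed the symbol of 36 and left 10 with the name in the files. THIOL, a peroxisomal 3-ketoacyl-CoA thiolase by its title, and BUG, whose gene is unknown here, kept their file names. The name FAS in the files belonged to the Fas receptor and was kept out of the lipid synthesis list. The positions of the spotted fragments within their genes are not given in the sources used here. Probes of close relatives (Cyp4a, Cyp2c, Cyp3a and Ugt1a genes) can bind each other's transcripts, so values of single members are uncertain in identity. The 4 genes Cidea, Cidec, Pck1 and Ppara had 2 spots each.

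Alternatives fixed beforehand were scaling by the median of mouse spots, scaling by the yeast spike-ins, the authors' values, no background correction, subtraction of the DMSO mean, no filter and a strict filter (all 10 arrays of a group above background, 110 probes), a fit to the compared groups alone, the replicate number as a block, and array weights. The authors' values differ from the reported fit both in scaling and in lacking background correction, so a change with them is not put down to scaling alone. Chosen after seeing the data were robust DMSO estimates, subtraction of signal spreading from neighbouring spots, leaving out the 7 tested probes with over 25% of their signal from neighbours by the estimate below, leaving out 7 arrays with outlying DMSO spots, and leaving out each array in turn. Spread from neighbours was estimated on the DMSO spots. A directly adjacent spot added a median 0.128% of its signal and a diagonal one 0.0328%. Predicted and observed DMSO signals correlated with r = 0.938 across spots, which are not independent replicates. The prediction was fitted on these same spots, so this r is no separate check of it. Numbers shared by replicates of different groups did not pair the animals.

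The pipeline was tested on simulated data made for the comparison of 200 mg/kg with vehicle in wild type, in 20 runs of 147 probes with 10 probes changed at each fold size. It recovered 48% of changes of 1.5-fold, 73.5% of 2-fold and 97.5% of 4-fold, with a mean of 3.9 of 117 unchanged probes called beside 21.9 recovered changes, and 0 calls where nothing was changed. The share of wrong calls among all calls thus exceeded the nominal 5% with quantile normalization when strong changes were present. With median scaling the mean of wrong calls in the same runs was 1, and recovery was 39%, 84% and 92%. The simulated changes held as many increases as decreases, and noise was independent between probes. These rates therefore do not cover changes that go mostly one way. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.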

Results

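Liver RNA from 60 male mice was hybridized to nylon macroarrays carrying 295 spots of mouse cDNA chosen by the authors, 1 mouse per array. Wild-type and PPARα-null mice each formed 3 groups of 10, given corn oil (vehicle) or DEHP at 20 or 200 mg/kg per day for 21 days. PPARα is a nuclear receptor activated by fatty acids and by peroxisome proliferators, and per its title the series asked what part it plays in the hepatic response to DEHP. The median DMSO signal per array ranged from 1655 to 3699 and the median mouse spot from 3241 to 5939. Between 51 and 156 mouse spots lay above background on an array (median 123, or 41.7% of the spots). Group means were 124.5, 129.8 and 132.6 spots in wild type and 104.2, 118.7 and 114.1 in null mice, at 0, 20 and 200 mg/kg. On a typical array most of these spots thus lay below this limit, and 147 probes were tested. The limit rises with the SD of the DMSO spots, whose median under vehicle was 1823 in null and 1274 in wild-type mice. The array with 51 spots above background had a DMSO SD of 10005 at a DMSO median of 2566. A lower count therefore does not by itself mean dimmer mouse spots.

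Ppara itself was represented by 2 spots. On the brighter, the normalized log2 signal in wild type was 12.14 ± 0.31 under vehicle, 12.06 ± 0.37 at 20 mg/kg and 12.34 ± 0.16 at 200 mg/kg (SD, n = 10 each), above background on 8, 8 and 10 of 10 arrays. In null mice it was 11.92 ± 0.28, 12.09 ± 0.25 and 11.79 ± 0.32, above background on 5, 7 and 4 arrays. The difference between genotypes under vehicle, -0.22 ± 0.13 (SE), did not pass the threshold (limma, adjusted p = 0.198). Nor did the change at 200 mg/kg in wild type of 0.21 ± 0.13 (adjusted p = 0.238), although it passed with spike-in scaling (0.53) and the authors' values (0.40). The other spot was above background on at most 1 array of a group, with group means from 10.76 to 11.04, and was not tested. Because the position of these fragments relative to the deleted part of the gene is not given, the Ppara signal checks neither the knockout nor the labels.

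The comparison of 200 mg/kg with vehicle in wild-type mice asked which of the chosen genes respond to DEHP when the receptor is present. Genes of peroxisomal and microsomal fatty acid oxidation rose most. Ehhadh, the bifunctional enzyme of peroxisomal β-oxidation, was 8.77-fold higher (95% interval 6.85 to 11.2, n = 10 mice per group, adjusted p = 2.59e-23). Transcripts of the fatty acid ω-hydroxylases were higher as well, Cyp4a14 by 8.43-fold (5.90 to 12.0), Cyp4a10 by 4.93-fold (3.65 to 6.66) and Cyp4a12b by 2.49-fold. For each of these 4 genes all 10 treated arrays lay above the vehicle mean.

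Of 11 tested members of the microsomal and peroxisomal oxidation list, 8 rose and 0 fell (9 and 0 adjusted over the list alone; fry adjusted p = 2.25e-18). Besides Ehhadh, Cyp4a14 and Cyp4a10 these included THIOL (3.45-fold, against a vehicle group with 1 array above background), Eci2 (1.48-fold), Hsd17b4 (1.35-fold) and Ech1 (1.29-fold). In the mitochondrial oxidation and ketogenesis list 3 of 10 rose and 1 fell, likewise adjusted over the list alone (fry adjusted p = 1.03e-11, up). Acot1, an acyl-CoA thioesterase, was 4.54-fold higher (3.37 to 6.13) and above background on 10 treated arrays but 1 vehicle array, so the size of this fold depends on the background correction. Also higher was Eci1, an enoyl-CoA isomerase (1.50-fold). Pdk4, a kinase that inhibits pyruvate dehydrogenase, was above background on 8 treated and 0 vehicle arrays and at least 1.97-fold higher (adjusted p = 1.81e-17). Acot1, Eci1 and Pdk4 were the only members called higher, so the list result does not show that the other members rose. The member that fell, Ucp3, lies beside a far brighter spot. The neighbour signal estimated for it, 202% of its own, is too high to be right, and it followed that neighbour within groups with r = 0.0751 only. The source of its signal is open, and its call ended under 5 alternatives, neighbour subtraction and spike-in scaling among them. Fabp1, the fatty acid binding protein of liver, was the 1 of 5 members of the uptake list that rose (1.58-fold, 1.25 to 2.00; 1 adjusted over the list alone), and the list moved up (fry adjusted p = 0.00260).

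Among sterol and lipid synthesis genes the changes were smaller. Fdps, an enzyme of the isoprenoid pathway, was 1.39-fold higher and the only one of 6 tested cholesterol genes past the threshold. Adjusted over the list alone 3 passed, with Hmgcs1 (0.38) and Fdft1 (0.43 on the log2 scale). The list moved up (fry adjusted p = 0.0365; not past the threshold with median scaling, no filter, the strict filter or array weights). In the fatty acid and triglyceride synthesis list 2 of 10 fell and 0 rose, likewise over the list alone, with no balance in one direction (fry adjusted p = 0.269, and up with the authors' values). These were Lpin1, a phosphatidate phosphatase, 2.32-fold lower (1.61 to 3.34), and the fatty acid elongase Elovl2, 1.45-fold lower. Fasn was above background on at most 3 of 10 arrays of any group and was not tested. Scd1 was 0.48 higher on the log2 scale without passing the threshold (adjusted p = 0.0718).

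Some members of the lipoprotein and bile acid lists and several other genes were lower in this fit. Most of the decreases ended with spike-in scaling, as given below. Apoa4, an apolipoprotein, was 2.54-fold lower (1.93 to 3.34, adjusted p = 8.82e-08). Of 13 tested members of the lipoprotein list 3 fell, Apoa4, Apoa5 (1.50-fold) and Apoe (1.43-fold), with 0 higher and the same counts adjusted over the list alone (fry adjusted p = 1.75e-09, down). The organic anion transporters Slco1a1 and Slco1a4 were the 2 of 12 members of the bile acid list that fell, 1.72-fold and 1.63-fold, again with the same counts adjusted over the list alone (fry adjusted p = 0.000333, down). In the glucose list of 6 probes, Pdk4 rose while both spots of Pck1, the gluconeogenic carboxykinase (1.81-fold on the brighter), and the glucose transporter Slc2a2 (1.38-fold) fell, with the same counts adjusted over the list alone. On balance the list did not move (fry adjusted p = 0.910), but it was called down with no filter, the strict filter and the fit to the compared groups alone (adjusted p from 5.73e-06 to 0.0442). Transferrin (Trf, 1.84-fold), the complement component C9 (1.81-fold), Gulo (1.49-fold), Got1 (1.45-fold), BUG (1.45-fold) and Hsd11b1 (1.39-fold) fell too, as did Hsd3b4, which was above background on 0 treated arrays and is given no fold.

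Genes of drug metabolism did not move as a group (1 of 11 higher and 2 lower, also adjusted over the list alone; fry adjusted p = 0.199). Alas1, the rate-limiting enzyme of heme synthesis, was 1.89-fold higher (1.22 to 2.95, 8 of 10 arrays), and Cyp2c40 and Ugt1a6b were 1.69-fold and 1.43-fold lower. Cyp3a11, a target of the receptor PXR, changed by -0.26 ± 0.24 (adjusted p = 0.418) and Cyp2c29 by 0.33 ± 0.14 (adjusted p = 0.0718), and Cyp2b10 was above background on no array of either group. The AhR and oxidative stress list moved down with 1 of 5 lower, Sod2 (1.28-fold; also adjusted over the list alone; fry adjusted p = 0.000201). Nuclear receptors (10 tested, fry adjusted p = 0.983, with a mean of 0.01 and a test direction of down) and reference transcripts (3 tested, fry adjusted p = 0.548) had 0 members past the threshold either way, as did the pairs of tested genes for inflammation and for the cell cycle.

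In all, limma called 16 probes higher and 21 lower (43.2% higher), and the direction of the smaller changes depended on the processing. The median change of all tested probes was -0.07, against 0.24 with spike-in scaling and 0.21 with the authors' values. The split became 44 higher and 4 lower (91.7% higher) and 44 and 2 (95.7%), while median scaling gave 17 and 22 (43.6%). All 16 increases were kept under these 3 alternatives, of which the authors' values also lack background correction. Of the 21 decreases 18 were kept with median scaling, 4 with spike-in scaling (Apoa4, Lpin1, C9 and Slco1a4) and 2 with the authors' values (Apoa4 and Lpin1). Apoe and Sod2 turned higher under the latter pair. The downward shifts of the lipoprotein, bile acid and AhR lists turned upward, short of the threshold, with those same alternatives, whereas nuclear receptors and reference transcripts moved up past it. Leaving out 1 array at a time ended 5 calls. These were Alas1 (without vehicle replicate 8 or treated replicates 2 or 3, adjusted p up to 0.0596), Fdps (vehicle 4 or treated 2, up to 0.0734), Ech1 (vehicle 1, 2, 3 or 10, treated 2, 5, 7 or 10, up to 0.0739), Elovl2 (vehicle 4, 7, 8 or 10, treated 1, 2, 3, 8 or 9, up to 0.0743) and Ucp3 (vehicle 1, 0.0631).

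**Figure D1:**
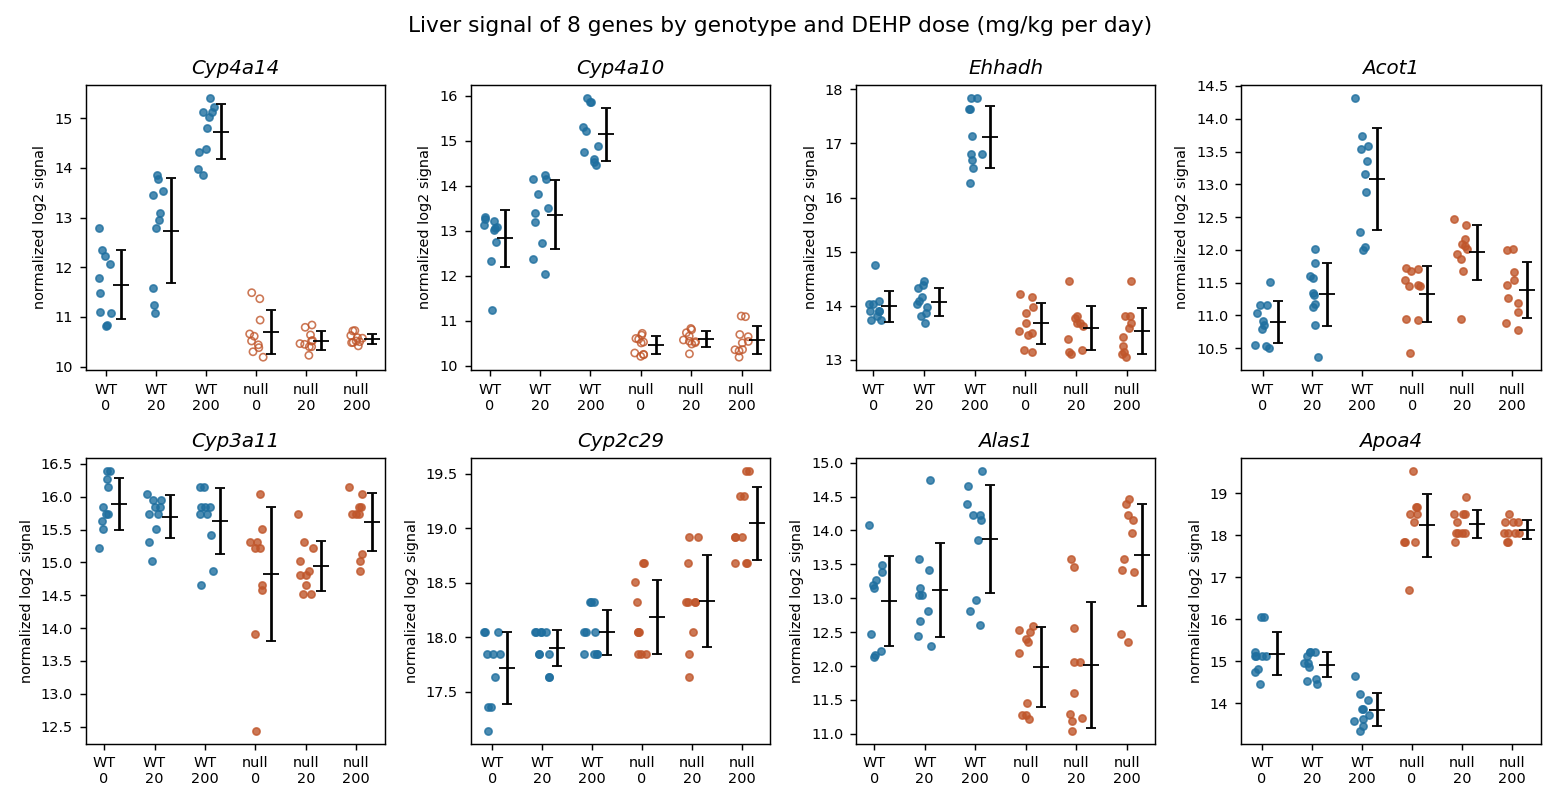
Normalized log2 signal (y axis) of 8 genes by genotype and DEHP dose in mg/kg per day (x axis), with 1 point per array, 10 arrays per group, blue for wild type and orange for PPARα-null mice, open circles for groups with no array above background, and bars for the mean ± SD. Ehhadh lay between 16.27 and 17.84 on the wild-type arrays at 200 mg/kg, above all vehicle arrays (13.73 to 14.74), and Apoa4 lay higher on every null array than on any wild-type array.

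The comparison of 20 mg/kg with vehicle in wild-type mice asked whether the lower dose changes the same genes. Cyp4a14 was 2.12-fold higher (1.48 to 3.02, n = 10 per group, adjusted p = 0.0130; 7 of 10 treated arrays above the vehicle mean) and was the only probe that passed the threshold. THIOL (0.56 ± 0.16, adjusted p = 0.0797) and Cyp4a10 (0.52 ± 0.22, adjusted p = 0.448) did not pass it, although THIOL did with the DMSO mean subtracted, with array weights and without the arrays with outlying DMSO spots. The value of Cyp4a10 is enlarged by vehicle replicate 10, at 11.23 against 13.01 ± 0.31 (SD) on the other 9 vehicle arrays. As a group, the 11 tested genes of microsomal and peroxisomal fatty acid oxidation moved up (mean 0.35 on the log2 scale, fry adjusted p = 0.000637), with 1 higher and 0 lower, and 3 and 0 adjusted over the list alone. This shift was not past the threshold with the authors' values. The other 11 tested lists did not move (fry adjusted p from 0.884 to 0.933), and among their members only 1 mitochondrial probe passed adjusted over its list alone. Mean and median had opposite signs in the mitochondrial, uptake, AhR and nuclear receptor lists.

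The single call at 20 mg/kg was fragile. The adjusted p for Cyp4a14 ranged from 0.000154 to 0.280 over the alternatives and missed the threshold with the authors' values (0.0526), in the fit to the compared groups alone (0.280), with robust DMSO estimates (0.161) and after neighbour subtraction (0.113). Leaving out vehicle replicate 4 or treated replicates 4, 6 or 8 left 0 calls (for Cyp4a14, 0.96 and adjusted p = 0.0652 without treated replicate 4). Leaving out vehicle replicates 1, 2, 7 or 9 or treated replicate 5 gave 2 calls, and without treated replicate 7 there were 3. The median change of all probes was 0.13 with spike-in scaling and 0.11 with the authors' values, against 0.02.

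The comparison of 200 mg/kg with vehicle in PPARα-null mice asked which responses remain without the receptor. Some genes of the drug metabolism list were higher. Alas1 was 3.16-fold higher (2.03 to 4.93, n = 10 per group, adjusted p = 0.000184), Cyp2c29, a cytochrome P450 of the CAR-responsive type, 1.82-fold (1.49 to 2.21, adjusted p = 1.37e-05) and Cyp3a11 1.73-fold (1.24 to 2.43, adjusted p = 0.0439), each above the vehicle mean on 10 of 10 treated arrays. Thrsp, a regulator of lipogenesis, was 1.72-fold higher (adjusted p = 0.00280; 9 of 10 arrays). It was above background on 7 treated arrays and 1 vehicle array, and its log2 change ranged from 0.56 to 1.01 over the alternatives. Lpin1 was 1.84-fold lower (adjusted p = 0.0430) and Angptl4, an inhibitor of lipoprotein lipase, 1.47-fold lower (adjusted p = 0.0295; above background on 1 treated and 4 vehicle arrays), each on 9 of 10 arrays.

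Drug metabolism was the only one of the 12 lists that moved in null mice at this dose, with 3 of 11 members higher and 0 lower, 4 and 1 adjusted over the list alone, and a mean of 0.37 (fry adjusted p = 0.000799, up). Cyp2a5 (0.63 ± 0.20) and Cyp2c40 (-0.50 ± 0.16) each had an adjusted p of 0.0513. Ehhadh, which rose in wild type, had a value of -0.14 ± 0.18 (adjusted p = 0.918). Cyp4a14, Cyp4a10, Pdk4 and THIOL were above background on no null array at this dose or under vehicle. The lists of peroxisomal (fry adjusted p = 0.702) and mitochondrial oxidation (0.686), cholesterol (0.602), bile acids (0.496), AhR (0.686), glucose (0.496), nuclear receptors (0.702) and reference transcripts (0.903) had 0 calls. Fatty acid synthesis had 1 higher and 1 lower, with 1 and 2 adjusted over the list alone (fry adjusted p = 0.496), lipoproteins 0 and 1 (0.394), and uptake none, with 0 and 2 adjusted over the list alone (0.496).

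Of these 6 calls, Alas1 and Cyp2c29 passed the threshold under all alternatives and with each array left out, although Cyp2c29 is among the brightest spots, whose values are set by rank. The log2 change of Alas1 ranged from 1.28 with no background correction to 1.85 with the DMSO mean subtracted. Cyp3a11 ranged from an adjusted p of 0.00226 to 0.376 over the alternatives. Its change dropped to 0.45 ± 0.22 (adjusted p = 0.376) without the 7 arrays with outlying DMSO spots. Its call also ended under 6 further alternatives and without vehicle replicates 3, 4, 6 or 10 or treated replicates 3, 4, 5, 7, 8 or 9, with 0.53 ± 0.20 and an adjusted p of 0.167 without vehicle replicate 6. The call of Lpin1 ended without vehicle replicates 4, 7, 8, 9 or 10 or treated replicates 1, 3, 4, 5, 8 or 10 (adjusted p up to 0.105), and that of Angptl4 without vehicle replicates 1 or 7 or treated replicates 3, 5, 7 or 8 (up to 0.0883). The count fell from 6 to 3 without treated replicates 3, 5 or 8. The split of 4 higher and 2 lower (66.7% higher) became 3 and 1 with median scaling, 3 and 0 with spike-in scaling and 10 and 0 with the authors' values, which also lack background correction. Thrsp missed the threshold with median and spike-in scaling, Lpin1 with all 3 and Angptl4 with the latter pair. In the fit to the compared groups alone these 3 calls ended too, as did those of Lpin1 and Angptl4 with no filter, of Lpin1 with array weights and of Angptl4 with the DMSO mean subtracted. The median change of all probes was 0.14 with spike-in scaling and 0.21 with the authors' values.

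At 20 mg/kg in PPARα-null mice limma called 0 probes, with 14 at an unadjusted p under 0.05. Among the lowest p-values were those of the lipid genes Acot1 (0.63 ± 0.22, 9 of 10 arrays above the vehicle mean) and Cpt2, a carnitine palmitoyltransferase (0.34 ± 0.13, 10 of 10), both with an adjusted p of 0.420. The mitochondrial oxidation and ketogenesis list moved up (mean 0.20, 3 of 10 members higher adjusted over the list alone, fry adjusted p = 0.00434), but not with median scaling, spike-in scaling, the authors' values or no filter. The other 11 lists did not move (fry adjusted p = 0.814 for each), and mean and median had opposite signs for fatty acid synthesis and nuclear receptors. The median change of all probes was -0.11 with spike-in scaling.

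Whether the response to 200 mg/kg depended on genotype was tested as an interaction, the change in null mice minus the change in wild type. The oxidation genes responded less in null mice. The interaction was -3.27 ± 0.25 for Ehhadh (log2, SE, n = 10 in each of 4 groups, adjusted p = 5.54e-17), -2.13 ± 0.31 for Acot1 (above background on 1 and 3 null arrays), -1.43 ± 0.21 for Cyp4a12b and -1.10 ± 0.24 for Fabp1. It was negative and past the threshold for Cyp4a14, Cyp4a10, Pdk4 and THIOL as well, whose null arms lay at background, so that no fold is given. Fabp2, a fatty acid binding protein best known from intestine, had -1.04 ± 0.31 (adjusted p = 0.0147). Genes with positive values, lower in wild type or higher in null mice, included Apoa4 (1.23 ± 0.28, adjusted p = 0.000643), Cyp3a11 (1.05 ± 0.34, adjusted p = 0.0248), Trf (1.05 ± 0.33), Got1 (1.01 ± 0.25) and C9 (0.87 ± 0.27).

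By list, the interaction was negative for peroxisomal and microsomal oxidation (0 higher and 5 lower of 11, 0 and 7 adjusted over the list alone, fry adjusted p = 6.08e-12), mitochondrial oxidation (0 and 3 of 10, 1.16e-06), uptake (0 and 2 of 5, 1 and 2 adjusted over the list alone, 0.00291) and cholesterol (0 and 0, 0.0357). It was positive for drug metabolism (2 and 0 of 11, 3 and 0 adjusted over the list alone, 0.000481), AhR (1 and 0, 2 and 0 adjusted over the list alone, 0.00196) and lipoproteins (2 and 1 of 13, 0.000515). Not past the threshold were fatty acid synthesis (0.889, mean -0.00 and median 0.04), bile acids (1 and 0, but 0 adjusted over the list alone, 0.107), glucose (0 and 1, 0.661, mean -0.05 and median 0.26), nuclear receptors (0.801) and reference transcripts (0.794). With no filter the bile acid list passed it with a positive interaction (fry adjusted p = 0.0213). The 3 members of the mitochondrial list called lower were Acot1, Pdk4 and Eci1. The interactions of Alas1 (0.74 ± 0.45, adjusted p = 0.291) and Cyp2c29 (0.53 ± 0.20, adjusted p = 0.0603, past the threshold only with array weights) were not called, so their change is not shown to differ between genotypes.

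The interaction split of 12 higher and 13 lower (48% higher) became 9 and 13 (40.9%) with median scaling, 1 and 14 (6.67%) with spike-in scaling and 1 and 11 (8.33%) with the authors' values. All 13 negative interactions were kept under median and spike-in scaling and 11 with the authors' values, while of the 12 positive ones 9, 1 and 1 were kept, the last being Apoa4 in both cases. Apoe, positive at 0.52, turned negative with spike-in scaling and the authors' values. The list calls for drug metabolism and AhR ended with spike-in scaling and the authors' values, and that for lipoproteins with these and median scaling (turning negative with spike-ins). That for mitochondrial oxidation ended with the authors' values, and that for cholesterol with 5 alternatives. The median interaction of all probes was 0.06, against 0.11 with median scaling, -0.08 with spike-in scaling, 0.00 with the authors' values and 0.16 with the DMSO mean subtracted.

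**Figure D2:**
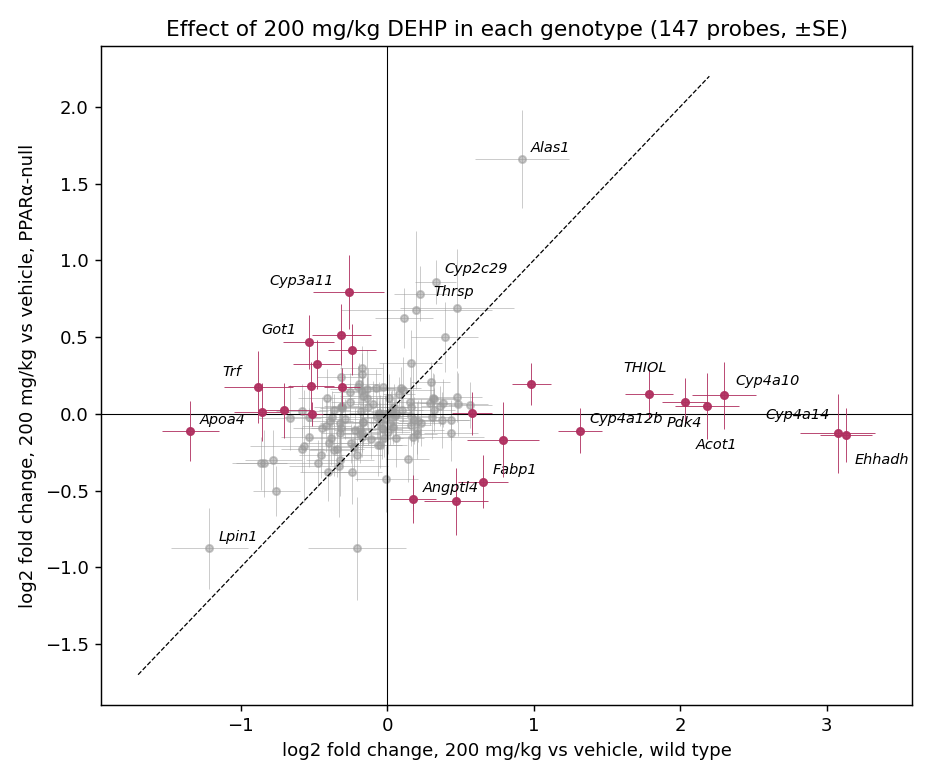
Log2 fold change at 200 mg/kg against vehicle in wild type (x axis) and in PPARα-null mice (y axis) for 147 probes with SE bars, n = 10 arrays per group. Coloured points passed the interaction test (25 probes, or 15 with spike-in scaling), the dashed line marks equal effects, and Ehhadh stood at 3.13 and -0.14 while Alas1 stood at 0.92 and 1.66.

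The interaction at 20 mg/kg asked whether the low dose acts differently in the genotypes, and limma called 0 probes (8 at an unadjusted p under 0.05). Cyp4a14, with null arms at background, Cyp4a12b (-0.73 ± 0.21), the peroxisomal enzyme Hsd17b4 (-0.61 ± 0.18) and Cbs (0.58 ± 0.17) each had an adjusted p of 0.0559. Cyp4a14 passed the threshold with median scaling, spike-in scaling and array weights, and THIOL with spike-in scaling. Neither the peroxisomal oxidation list (fry adjusted p = 0.0670, 0 higher and 2 lower adjusted over the list alone) nor the mitochondrial list (0.0801, 1 and 0) passed, although the peroxisomal list did with array weights and both did in the fit to the compared groups alone. The other lists gave adjusted p-values from 0.824 to 0.993 (mean and median of opposite sign for uptake, AhR and nuclear receptors). Whether the response of Cyp4a14 at 20 mg/kg differs between genotypes thus depended on the processing. Leaving out wild-type vehicle replicates 1 or 4 gave 1 and 2 calls, and leaving out wild-type 20 mg/kg replicates 1, 3 or 7 gave 2, 1 and 4. The median interaction of all probes was -0.22 with spike-in scaling and -0.15 with the authors' values.

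The comparison of null with wild-type mice under vehicle asked which genes depend on the receptor without DEHP, with age differing alongside genotype. Genes of fatty acid oxidation were lower in null mice. Ech1, an isomerase of unsaturated fatty acid oxidation, was 3.68-fold lower (3.06 to 4.42, n = 10 per group, adjusted p = 5.10e-19), Cpt2 2.17-fold (1.80 to 2.60) and Eci2 2.07-fold. Cyp4a10 was above background on 9 wild-type and 0 null arrays and at least 1.61-fold lower. Cyp4a14, above background on 5 and 0 arrays, passed the threshold (adjusted p = 0.00153) with no fold that could be given, though not with median or spike-in scaling. Apoa4 was 8.32-fold higher in null mice (6.33 to 10.9, adjusted p = 1.54e-20), on 10 of 10 arrays, where it is among the brightest spots, whose values are set by rank.

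The lists of peroxisomal and microsomal oxidation (1 higher, 6 lower of 11) and mitochondrial oxidation (0 and 4 of 10, with Ucp3, whose call ended after neighbour subtraction) moved down with the same fry adjusted p of 7.56e-11. Counts adjusted over the list alone equalled these and all others given here for the genotypes. Cyp4a12b (1.65-fold) and Hsd17b4 (1.34-fold) went the other way, the latter as the 1 higher member of its list, a call that ended with median scaling, spike-in scaling and the authors' values. Fatty acid synthesis genes were lower (1 higher and 6 lower of 10, fry adjusted p = 9.58e-10), among them the desaturases Scd1 (3.72-fold, 2.79 to 4.95) and Fads2 (1.97-fold) and the elongase Elovl3 (2.48-fold), while Thrsp passed the threshold as higher, with 1 null and 0 wild-type arrays above background and so no fold, a call that ended with the DMSO mean subtracted (adjusted p = 0.325, from 0.000104 upward over the alternatives). The uptake list moved down (0 and 1 of 5, Vldlr at 2.03-fold, 0.00156), as did glucose (0 and 1 of 6, G6pc, 0.0110), neither of them with spike-in scaling or the authors' values, nor glucose with median scaling, nor uptake with no filter.

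Sterol and bile acid genes were higher in null mice. Of 12 tested members of the bile acid list 6 were higher and 0 lower (fry adjusted p = 7.56e-11), led by Cyp7b1, an oxysterol hydroxylase (2.90-fold, 2.17 to 3.87), and Slco1a4 (2.57-fold). The cholesterol list had 3 of 6 higher and 0 lower (3.28e-05), Fdps (1.72-fold), Fdft1 (1.68-fold) and Hmgcs1 (1.48-fold). In drug metabolism 2 were higher and 2 lower (0.130), although the list was called up without the arrays with outlying DMSO spots (fry adjusted p = 0.0255). Cyp2a5 was above background on 6 null and 0 wild-type arrays and at least 1.39-fold higher, and Cyp2c29 was 1.39-fold higher. In contrast, Cyp3a11 was 2.09-fold lower (1.50 to 2.93) and Alas1 1.97-fold lower, the call of Alas1 ending with spike-in scaling and the authors' values. Null vehicle replicate 6, an array with outlying DMSO spots, enlarges the Cyp3a11 fold (signal 12.44, next lowest 13.91). The call of Cyp3a11 was kept with each array left out. Cyp1a1 was 2.04-fold higher and the 1 member called in the AhR list (0.0313, up, with a median of -0.02), a list call that ended under 7 alternatives. Nuclear receptors had 2 higher and 3 lower (0.215), with Thra and Vdr 1.80-fold and 1.79-fold lower and Nr1i3, which encodes CAR, 1.50-fold higher. Lipoproteins had 3 and 3 (0.0881) with Angptl4 2.64-fold lower, reference transcripts 0 and 0 (0.215), inflammation 0 and 0 of 2, and the cell cycle list 0 and 1 of 2, Cdkn1a at 2.00-fold lower. With robust DMSO estimates the lipoprotein list was called up (fry adjusted p = 0.0394).

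Folds of Cpt2, Vldlr, Cdkn1a, Thra and Vdr rest on 1 or 2 null arrays above background, and those of Cyp7b1 and Hmgcs1 on 1 or 2 wild-type arrays. In total 27 probes were higher and 28 lower (49.1% higher), 25 and 26 with median scaling, 29 and 19 (60.4%) with spike-in scaling and 25 and 23 with the authors' values. Ikbkg, 2.52-fold higher, lies beside the brighter spot Mup2 and lost its call when neighbour signal was subtracted. Leaving out 1 array ended the calls of Elovl2 (wild-type replicate 10 or null replicates 3 or 8, adjusted p up to 0.0689), G6pc (wild-type replicate 3, 0.0550) and THIOL (15 of the 20 arrays, up to 0.136 without wild-type replicate 1). THIOL, called lower with 1 wild-type and 0 null arrays above background, turned higher with spike-in scaling. Among markers of other cell types, the bile duct gene Spp1 (0.36 ± 0.18) did not pass the threshold (adjusted p = 0.112). None of the macrophage and endothelial markers on the list was spotted, and over all comparisons only Fabp1 and Fabp2, listed as hepatocyte and intestine markers, were called.

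**Figure D3:**
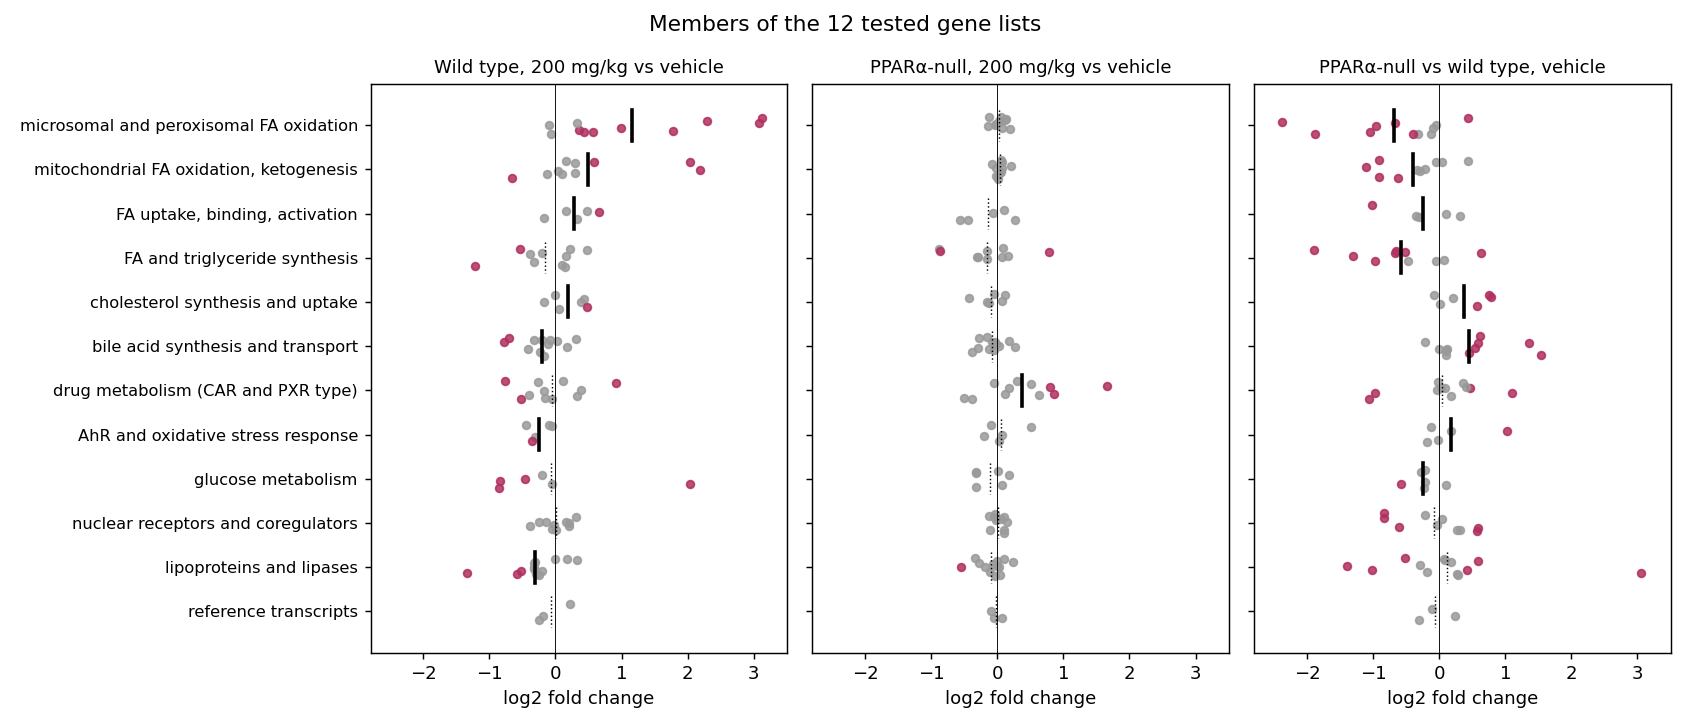
Log2 fold change (x axis) of the tested members of 12 gene lists at 200 mg/kg against vehicle in wild type and in PPARα-null mice and in null against wild-type mice under vehicle, 1 point per probe, n = 10 arrays per group. Coloured points passed the adjusted p of 0.05, thick lines mark list means with a fry adjusted p under 0.05 and dotted lines the other means, which were 1.16 for microsomal and peroxisomal oxidation in wild type at 200 mg/kg and 0.37 for drug metabolism in null mice, while the downward means of lipoproteins, bile acids and AhR in wild type turned upward with spike-in scaling.

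The contrast of 200 with 20 mg/kg asked where the higher dose added to the lower. In wild type Ehhadh was 8.25-fold higher at 200 mg/kg (6.44 to 10.6, n = 10 per group), Cyp4a14 3.99-fold, Cyp4a10 3.44-fold, Acot1 3.40-fold, THIOL 2.34-fold and Pdk4 at least 2.09-fold. Lpin1 was 2.39-fold lower, Apoa4 2.10-fold, Hsd11b1 1.72-fold and C9 1.71-fold. Peroxisomal (5 of 11 higher, fry adjusted p = 1.03e-11) and mitochondrial oxidation (4 of 10, 2.35e-11) and uptake (2 of 5, 0.00150) moved up. Bile acids (1 higher, 3 lower, 0.00467), AhR (0 and 1, 0.00271) and lipoproteins (0 and 5, 1.24e-08) moved down, the last 3 turning upward short of the threshold with spike-in scaling and the authors' values. The bile acid and AhR calls ended with median scaling too, and that for bile acids with the DMSO mean subtracted. Fatty acid synthesis (1 and 1, 0.734, mean -0.05, median 0.01), cholesterol (0.213, but past the threshold and up with spike-in scaling and the authors' values), drug metabolism (0 and 2, 0.0948), glucose (1 and 3, 0.734, up by the test, median -0.36), nuclear receptors (0 and 1, 0.714) and reference transcripts (1 and 1, 0.673) did not pass. Actb was 1.30-fold higher and Gapdh 1.36-fold lower, the latter not with median scaling, spike-in scaling or the authors' values. The split of 18 higher and 24 lower (42.9% higher) became 13 and 16 (44.8%) with median scaling, 29 and 5 (85.3%) with spike-ins and 28 and 4 (87.5%) with the authors' values, whose median changes over all probes were 0.13 and 0.11. Leaving out 1 array ended 12 of these 42 calls, among the genes named here only that of Actb (20 mg/kg replicates 1 or 4, 200 mg/kg replicates 4, 7 or 10, adjusted p up to 0.0872), which also ended in the fit to the compared groups alone and without the arrays with outlying DMSO spots.

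In null mice Alas1 was 3.10-fold (1.99 to 4.83) and Cyp2c29 1.64-fold higher at 200 than at 20 mg/kg, with the same adjusted p of 0.000348, and Thrsp was 1.55-fold higher (adjusted p = 0.0428). No probe was called lower. Drug metabolism moved up (2 and 0, 4 and 0 adjusted over the list alone, fry adjusted p = 0.00277), and mitochondrial oxidation (0 and 0, 0 and 2 adjusted over the list alone) and lipoproteins (0 and 0) moved down with an adjusted p of 0.0108 each, both turning upward with spike-in scaling and the authors' values. Both calls ended with no filter, and the mitochondrial one with median scaling. The other lists gave 0.346 to 0.844, with Thrsp as the only call, and mean and median of opposite sign for peroxisomal oxidation, AhR and nuclear receptors. Reference transcripts and nuclear receptors were called up with spike-in scaling, and with the authors' values these, peroxisomal oxidation, AhR, fatty acid synthesis and bile acids were. The count of 3 was 1 with median scaling, 6 with spike-ins and 23 with the authors' values, all higher. The median change of all probes was 0.22 and 0.24 under the latter pair. The call of Cyp2c29 ended with median scaling, and that of Thrsp under 8 alternatives (adjusted p up to 0.237, from 0.00585 upward over all alternatives) and without 20 mg/kg replicates 2, 4, 5, 6, 9 or 10 or 200 mg/kg replicates 1, 2, 5, 7, 9 or 10 (adjusted p up to 0.156). Leaving out 20 mg/kg replicate 3 gave 5 calls.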

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

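The comparison of DMSO spots beside Mup2 and the counts over regrouped arrays were planned before their results were seen, while the tests of spike-in signal, unscaled mouse signal, neighbour subtraction, scaling of the drug-metabolism genes, outlying arrays and the list mean were chosen afterwards, as was leaving out each array.

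For 25 probes, 24 of them given here, the response to 200 mg/kg differed between genotypes by the interaction test (null minus wild type, log2 ± SE). Negative values were found for the oxidation and lipid genes Ehhadh (-3.27 ± 0.25), Acot1 (-2.13 ± 0.31), Cyp4a12b (-1.43 ± 0.21), Fabp1 (-1.10 ± 0.24), Fabp2 (-1.04 ± 0.31), Angptl4 (-0.73 ± 0.22) and Eci1 (-0.58 ± 0.20), and for Lef1 (-0.96 ± 0.35). Negative differences of signal, which measure no fold because 0 null arrays lay above background, were found for Cyp4a14 (-3.20 ± 0.36), Cyp4a10 (-2.18 ± 0.31), Pdk4 (-1.96 ± 0.22) and THIOL (-1.66 ± 0.23). Acot1 was above background on 1 null vehicle array and 3 at 200 mg/kg. Angptl4 changed in null mice (-0.56, adjusted p = 0.0295) and had 0.18 in wild type (adjusted p = 0.390), and Fabp2 had values of opposite sign (0.47 in wild type, -0.57 in null mice) of which neither passed. Lef1, with 53.3% of its signal from neighbours by the estimate, lost its call under 7 alternatives (adjusted p from 0.0142 to 0.314 over all), with the highest p after neighbour subtraction. Positive values were found for Apoa4 (1.23 ± 0.28), Cyp3a11 (1.05 ± 0.34), Trf (1.05 ± 0.33), Got1 (1.01 ± 0.25), C9 (0.87 ± 0.27), Cyp1a1 (0.83 ± 0.28), Hsd11b1 (0.80 ± 0.23), Slco1a4 (0.72 ± 0.25), Ugt1a6b (0.70 ± 0.22), Cybb (0.66 ± 0.23), Apoe (0.52 ± 0.11, negative with spike-in scaling and the authors' values) and Cbs (0.48 ± 0.17). Leaving out single arrays, 40 in turn, ended 6 of these calls. They were Cbs (25 arrays, adjusted p up to 0.0944 without null vehicle replicate 9), Lef1 (22 arrays, 0.0902 without wild-type 200 mg/kg replicate 8), Slco1a4 (16 arrays, 0.0710 without null vehicle replicate 6), Cybb (14 arrays, 0.0873 without null vehicle replicate 8), Cyp1a1 (wild-type vehicle 1 or 3, wild-type 200 mg/kg 4 or 6, null vehicle 2, null 200 mg/kg 2, 5, 7 or 10, up to 0.0699) and Eci1 (wild-type vehicle 1 or 2, wild-type 200 mg/kg 6 or 8, null vehicle 7, null 200 mg/kg 8 or 10, up to 0.0617). Without the arrays with outlying DMSO spots the calls of Cyp3a11, Trf, Cyp1a1, Slco1a4 and Eci1 ended.

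A single array stood apart from the others of its group for 2 of 36 group values examined by Dixon's ratio, against 1.8 by chance at 1 in 20. Ppara (brighter spot) in wild type at 20 mg/kg was 11.17 on replicate 7 against 12.16 ± 0.21 on the other 9 arrays. Cyp4a10 in wild type under vehicle was 11.23 on replicate 10 against 13.01 ± 0.31.

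The count of probes past the threshold was compared with 100 splits of the same arrays into groups of equal size, the real one included. As many probes were called by 1 of the 100 splits, the real one itself, at 200 mg/kg in wild type (37 probes, highest other 16), for genotype under vehicle (55 and 32), for the interaction at 200 mg/kg (25 and 4) and for 200 against 20 mg/kg in wild type (42 and 12). Chance is argued against for these counts, as far as 100 splits can show. In null mice 2 splits reached the 6 probes at 200 mg/kg (highest other 9) and 3 splits the 3 probes at 200 against 20 mg/kg (highest other 3). These shares lie under 0.05. In each case, however, a split other than the real one called as many probes or more, so chance is not excluded for these counts. At 20 mg/kg in wild type 10 splits reached the 1 probe (highest other 2) and chance cannot be excluded. The counts of 0 at 20 mg/kg in null mice and for the interaction at 20 mg/kg (limma, with 14 and 8 probes at an unadjusted p under 0.05) are reached by any split, 100 of 100, so this comparison says nothing about them (highest others 5 and 2).

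The first pattern weighed was the turn to mostly higher calls at 200 mg/kg in wild type with spike-in scaling, from 43.2% to 91.7% higher. Less spike-in signal on the treated arrays may account for it, and the spike-ins were 16.62 ± 0.31 against 16.78 ± 0.21 under vehicle, a difference of -0.16 (permutation p = 0.190). More labelled mouse cDNA on those arrays may do so as well, and the unscaled median of tested mouse probes was 13.10 ± 0.33 against 12.91 ± 0.16, a difference of 0.19 (permutation p = 0.121). Against median scaling, spike-in scaling raises every change by the mouse difference minus the spike-in difference. Both are therefore parts of that shift by construction and not rival explanations. Neither difference passed its permutation test, so neither is shown to exceed the spread among arrays. The combined difference was not tested, so these tests do not show whether the shift itself exceeds that spread. Whether the smaller decreases in wild type are real is open.

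The second pattern was the change of a dim probe beside a bright spot, Ikbkg beside Mup2, between genotypes under vehicle. Empty DMSO spots touching Mup2 (6, against 445 others) showed an excess of 2.19 ± 0.45 in null and 1.22 ± 0.31 in wild-type mice, a difference of 0.97 (permutation p = 0.00014), so signal spreading from Mup2 changed between genotypes. Ikbkg followed Mup2 within groups (r = 0.769), and its estimated neighbour share of 112% is too high to be right. A change in its own transcript stays open, since that share leaves the 0.88 ± 0.49 found after subtraction unable to decide (adjusted p = 0.165, against at most 1.86e-05 and at least 1.57e-08 under its other alternatives). Ikbkg is therefore not read as changed.

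The third pattern was the rise of Alas1, Cyp2c29 and Cyp3a11 at 200 mg/kg in null mice. Array scaling is argued against, because 3 of these 3 genes passed the threshold under each of median scaling, spike-in scaling and the authors' values. With the latter pair the median change of all probes was 0.14 and 0.21, which favours increases. The argument therefore rests on median scaling, where that median was -0.03. The arrays with outlying DMSO spots are argued against for Alas1 and Cyp2c29, the lower change without them being 0.90, but not for Cyp3a11, whose change fell from 0.79 ± 0.24 to 0.45 ± 0.22 without them and lost its call. A response that does not need PPARα may account for the rise of Alas1 and Cyp2c29. Under vehicle Alas1 and Cyp3a11 were lower in null than in wild-type mice in the reported fit, while Cyp2c29 was higher. The rises of Alas1 and Cyp3a11 thus began from a lower level, and Alas1 rose in wild type too. The list mean of 0.37 over 11 members includes Alas1, Cyp2c29 and Cyp3a11 themselves. It is thus no separate support and does not show that the other members rose. This remains a hypothesis found and tested on the same arrays, and binding of related P450 transcripts to these probes was not tested.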

How the results depend on the processing

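The robust DMSO estimates, the neighbour subtraction, the removal of probes lit by neighbours or of arrays with outlying DMSO spots, and leaving out each array were chosen after seeing the data. Over the comparisons and alternatives, leaving out each array included, 304 counts stayed within 1.5 times the reported count and 42 did not. The totals that follow for gene lists and named genes do not include leaving out single arrays. Of the gene list tests 1429 kept direction and side of the threshold, 40 lost the call, 15 gained one and 28 reversed, and of the named genes 4976 kept both, 154 lost the call, 95 gained one and 11 reversed. All alternatives fixed beforehand were run. Signal over background limits which genes could be compared: mouse spots above background ranged from 51 to 156 per array, 147 of 295 were tested, and folds against groups with no array above background are bounds only. Where a result below depended on the processing, the cause was not tested.

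Counts that moved were, for 20 mg/kg in wild type (1 reported), 2 with median scaling, 0 with the authors' values, 2 with the DMSO mean subtracted, 0 in the fit to only the compared groups, 2 with array weights, 0 with robust DMSO estimates, 0 with neighbour signal subtracted and 2 without arrays with outlying DMSO spots. For 20 mg/kg in null mice (0) they were 1 with median scaling and 1 with the DMSO mean subtracted. For 200 mg/kg in null mice (6) they were 3 with spike-in scaling, 10 with the authors' values, 3 with no filter on dim probes and 2 with only the compared groups. The interaction at 20 mg/kg (0) gave 1 with median scaling, 2 with spike-in scaling, 1 with the DMSO mean subtracted and 1 with array weights, that at 200 mg/kg (25) gave 15 with spike-in scaling and 12 with the authors' values, and 200 against 20 mg/kg in null mice (3) gave 1 with median scaling, 6 with spike-in scaling and 23 with the authors' values.

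With each array left out in turn the counts ranged from 0 to 3 at 20 mg/kg and 35 to 42 at 200 mg/kg in wild type, 0 to 0 and 3 to 9 in null mice, 53 to 57 for genotype, 0 to 4 and 20 to 25 for the interactions at 20 and 200 mg/kg, and 36 to 44 and 2 to 5 for 200 against 20 mg/kg in wild type and null mice. The counts beyond 1.5 times the reported one are named by array with each comparison.

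Replicate numbers did not pair the animals, since the 150 pairs of arrays sharing a number had correlations of their residuals from -0.40 to 0.44 with a mean of 0.01, and 9 of 60 arrays correlated best with their own number against 6 by chance. With the replicate number as a block the counts were 1 and 38 in wild type, 0 and 5 in null mice, 55 for genotype, 0 and 23 for the interactions, and 41 and 4 for 200 against 20 mg/kg.

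Gene lists that turned direction with spike-in scaling and with the authors' values, in this order, had adjusted p-values at 200 mg/kg in wild type of 0.235 and 0.252 for bile acids, 0.367 and 0.304 for AhR, 0.00556 and 0.0185 for nuclear receptors, 0.272 and 0.277 for lipoproteins and 0.00952 and 0.0119 for reference transcripts, and 0.0329 for fatty acid synthesis with the authors' values alone, all up. At 200 against 20 mg/kg in wild type they were 0.855 and 0.700 for bile acids and for AhR alike, and 0.894 and 0.855 for lipoproteins, all up. In null mice they were 0.423 and 0.180 for mitochondrial oxidation, 0.0450 and 0.00965 for nuclear receptors and 0.423 and 0.220 for lipoproteins, and with the authors' values alone 0.00965 for fatty acid synthesis and 0.0167 for bile acids, all up. In the interaction at 200 mg/kg lipoproteins turned down with spike-in scaling (0.775). With the strict filter on dim probes, which tests fewer genes, the glucose list turned up in that interaction (0.00585) and down at 200 against 20 mg/kg in wild type (0.000413).

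Among the genes of the naming rule those that turned direction, in the same order, were Sod2 at 0.15 and 0.14 and Apoe at 0.32 and 0.32 for 200 mg/kg in wild type, Apoe at -0.078 and -0.077 in the interaction at 200 mg/kg, and for 200 against 20 mg/kg in wild type Sod2 at 0.074 and 0.072 and Apoe at 0.19 and 0.19, the latter also with median scaling (0.0205). Outside that rule, THIOL turned higher between genotypes with spike-in scaling.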

Other observations

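Genes outside the lists also differed between genotypes under vehicle. The retinoic acid receptor gene Rarg was 1.97-fold higher in null mice, the major urinary protein gene Mup2 1.64-fold, Gulo, which encodes the last enzyme of vitamin C synthesis, 1.55-fold, and the glucocorticoid-activating enzyme gene Hsd11b1 1.46-fold (n = 10 per group). Gulo and Hsd11b1 were chosen for mention after their values were seen, and Mup2 is among the brightest spots, whose values quantile normalization sets by rank.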
